A study of Danio rerio with 6 samples.

How the data were processed

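A total of 6 pools of total RNA from zebrafish larvae were measured, each on its own Affymetrix zebrafish expression array, a single-colour array hybridised with biotin-labelled cRNA. Larvae had been injected at 2 days post fertilisation (dpf) with phosphate-buffered saline (PBS) or with live Salmonella Typhimurium, and their trunks were dissected at 4 dpf, with about 50 trunks in a sample. Per the labels, there were 3 biological replicates of each group, and the arrays were assigned to PBS or Salmonella from the sample titles alone. What distinguishes the replicates, such as the clutch or the day, is not given in the sources used here, nor are scan dates. P-values therefore rest on the spread between these samples, moderated over probe sets, and not on a known biological unit.

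The deposited values are log2 expression values made with RMA, per the submitters' processing notes, which give no software or version. RMA corrects the background, normalises arrays to a common distribution and summarises the probes of a probe set by a robust fit, which compresses differences between dim probe sets. The deposited table held 15617 probe sets for all 6 arrays, with array medians near 5.9 to 6.0 and no per-sample column left unused. Scanner-level data were not used here, so neither the background step nor a detection call could be repeated, and a low value is described as low and not as absent. Arrays give no counting depth. Their number, 3 in a group, limits the precision, and the median residual SD of a probe set was 0.15 in log2 units.

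Gene names came from the array annotation of 2016, updated through gene identifiers to the RefSeq names of the GRCz12tu assembly, which was used for names only. After 115 control probe sets had been set aside, 15502 probe sets were tested. Of these, 10795 carried 1 gene, 135 several and 4572 none, and 10711 probe sets had a gene identifier found in the RefSeq table. Probe sets with several genes or none were tested but not named. The 8793 genes included 1539 with more than 1 probe set, and each gene was represented by the probe set with the highest mean over the 6 arrays. Probes can cross-hybridise with close paralogs, which the values cannot separate.

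Before the data were examined, the groups, the test, the gene lists, the rule for named genes and most of the other settings were fixed. The comparison of Salmonella with PBS used limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariate), with Benjamini-Hochberg adjustment over all probe sets and a threshold of 0.05. Log2 changes are Salmonella minus PBS, and every adjusted p for a gene is from limma. The SEs and p-values are moderated, as eBayes draws the variance of each probe set toward a value shared over all probe sets. With few arrays in a group, they can differ much from the spread of a gene's own arrays. Gene lists were tested with camera, which asks whether a list moves against the other genes, with a preset correlation between genes of 0.01 and adjustment over 29 lists. The 30 lists held 1026 entries, 620 of them measured, and the tissue inhibitors of metalloproteinases fell below the minimum of 3 measured genes. Members were counted over all probe sets and also adjusted over the list alone. Camera with an estimated correlation, and fry, which asks whether the genes of a list move one way on balance, were run beside it. With an estimated correlation, camera uses the residual degrees of freedom, which are few with 3 or 2 arrays in a group. A call lost there can reflect those few degrees of freedom as well as correlated genes. The named genes were the measured genes of the study question, the 12 largest changes in each direction past the threshold with no overlap between the groups, the 5 with the smallest p where fewer than 5 passed, and up to 4 called members of each list or the 2 with the smallest p. Other genes were named only where they complete a count, or in the passages on list members and clock genes, chosen after their values were seen.

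A comparison restricted to replicate numbers 2 and 3, with 2 arrays in a group, was added after the arrays of replicate number 1 had been seen to run against the others. Its adjusted p-values are conditional on that choice and do not account for it. The same omission was run for each of the other replicate numbers. Further alternatives were the replicate number as a block, each array left out in turn, quantile normalisation run again, centring of each array on its median, removal of probe sets below the 25th percentile of mean signal, trended and robust eBayes, array weights, a minimum log2 change of 1, an adjusted p threshold of 0.1, an unmoderated per-probe-set test with unequal variances, the mean over a gene's probe sets, and camera on ranks.

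The procedure was tested on simulated data made for the 15502 probe sets. For 3 arrays against 3, it recovered 96% of 100 probe sets changed by 1 log2 unit and 99% of 100 changed by 2, with 11 false calls among 15282 unchanged. For 2 against 2, it recovered 84% and 100%, with 7 false calls. A planted list of 20 genes shifted by 0.5 was found in both, and 0 of 29 other lists were called. That count holds for the simulated data only. Divisions of the real arrays into 3 and 3 other than the labelled one called from 0 to 16 lists. Such divisions can still hold true differences. The simulation therefore does not show how often camera calls a list in real arrays without a true change.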

Results

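Expression was measured in dissected trunks of larval zebrafish 2 days after an injection of PBS or of live Salmonella Typhimurium, a bacterium that causes systemic infection in larvae. Each group had 3 arrays, numbered 1 to 3. The series concerns epidermal cells that help guide leukocytes by making matrix metalloproteinases, enzymes that cleave extracellular matrix, with fatty acids as their fuel. The comparison asks which transcripts of the trunk differ between infected and PBS-injected larvae. Array medians lay between 5.89 and 5.98 log2 units, and correlations between arrays across probe sets ranged from 0.987 to 0.996.

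In the comparison of all 6 arrays as labelled, no gene passed the threshold between Salmonella and PBS, and the 2 arrays of replicate number 1 ran against the other 4. lyz, which encodes lysozyme and marks neutrophils and other myeloid cells, averaged 9.77 ± 1.54 (SD, n = 3) in PBS and 11.11 ± 1.84 (SD, n = 3) in Salmonella on the log2 scale. By array, lyz stood at 8.78 and 8.98 in PBS replicates 2 and 3, but at 11.55 in the array labelled PBS replicate 1. It stood at 12.19 and 12.15 in Salmonella replicates 2 and 3, but at 8.99 in the array labelled Salmonella replicate 1. The Salmonella minus PBS difference of mpx, the myeloid peroxidase of neutrophils, was 2.58 for number 2, 3.16 for number 3 and -2.19 for number 1. For the collagenase gene mmp13a these differences were 2.01, 2.07 and -1.70, and for the clock gene per2 they were -2.34, -3.11 and 1.86. Across the 15502 probe sets, the differences of numbers 2 and 3 had a Pearson r of 0.261 (Spearman rho 0.181). That of number 1 had r = -0.309 with number 2 (rho -0.235) and r = -0.235 with number 3 (rho -0.119). These are correlations across probe sets, which are not independent replicates.

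**Figure D1:**
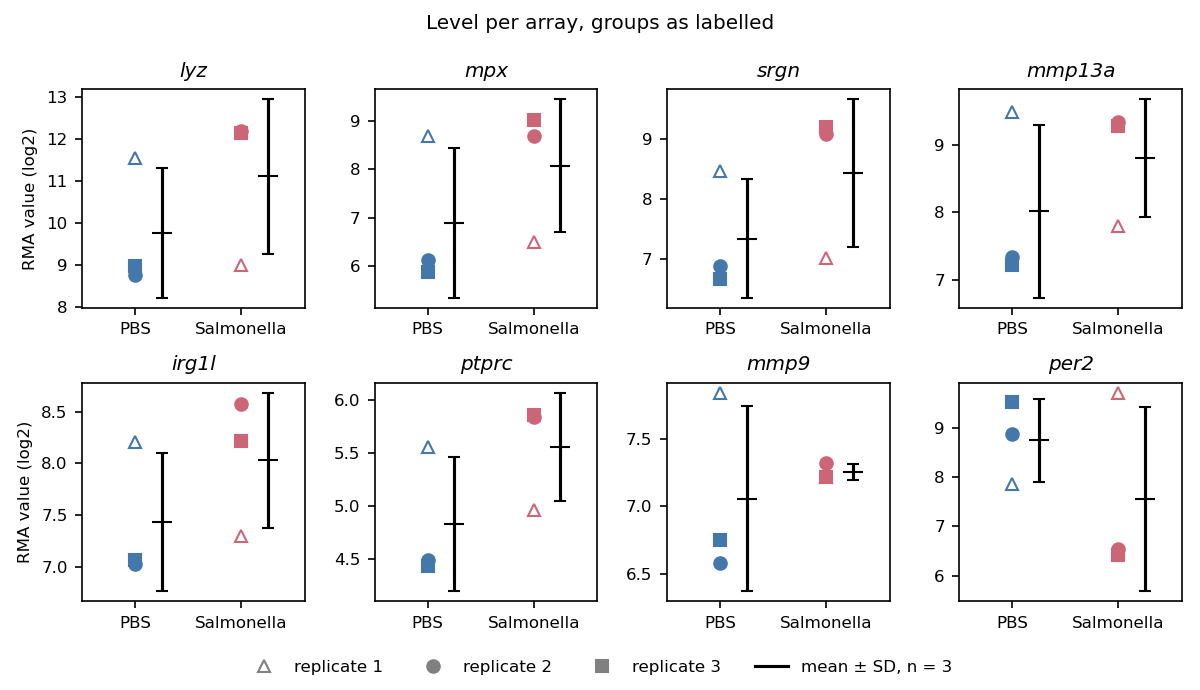
Deposited log2 values (vertical axes) of 8 genes in the 6 arrays, grouped as labelled, with open triangles for replicate 1, circles for replicate 2 and squares for replicate 3, and the group mean ± SD (n = 3) beside them. For lyz, mpx, srgn, mmp13a, irg1l and ptprc the open triangle labelled PBS lies above PBS replicates 2 and 3 and the open triangle labelled Salmonella below Salmonella replicates 2 and 3; lyz, for example, is at 11.55 and 8.99 in these arrays.

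By limma, 0 probe sets were higher and 0 lower at the adjusted threshold, and the smallest adjusted p was 0.994. At an unadjusted p under 0.05 there were 400 probe sets, against 775 given by chance, and the unmoderated test also called 0. Among the genes of the study question, mmp13a differed by 0.79 (SE 0.62), irg1l by 0.59 (SE 0.38), mmp9 by 0.20 (SE 0.29) and cebpb by -0.35 (SE 0.26), all with adjusted p = 0.994 in limma. mmp14a, mmp14b, cpt1b, hadhaa and saa differed by 0.17, 0.14, 0.11, -0.10 and 0.06, and none passed. mmp13b, acod1, il1b and cpt1aa were not named by the array annotation and were not analysed here. The smallest p-values among higher genes belonged to g2e3 (0.42), slc1a4 (0.38), pkp3a (0.32), nrxn2a (0.37) and vps33a (0.38), and among lower genes to LOC559664 (-0.60), slit3 (-0.40), ckap5 (-0.37), pih1d2 (-0.36) and hdac10 (-0.30). None of these 10 passed (adjusted p = 0.994). With both arrays of number 1 left out, 28 probe sets were higher and 4 lower, whereas leaving out number 2 or number 3 gave 0 in both directions.

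By gene list, 6 were higher and 1 lower by camera with the preset correlation, with no member of any list passing the test on its own. The list of neutrophil markers had a median change of 0.47 over 10 genes (adjusted p = 0.000119), and pan-leukocyte markers of 0.26 over 13 genes (adjusted p = 0.00582). Glucocorticoid-responsive genes had a median of 0.17 (adjusted p = 0.013), epidermis markers of 0.04 (0.00582), immediate early and stress transcription factors of 0.09 (0.048), and cartilage, bone and notochord markers of 0.03 (0.048). Oxidative phosphorylation genes had a median of -0.07 (adjusted p = 0.048). With an estimated correlation 0 of the 7 lists held, with adjusted p = 0.830 for the lists other than the immediate early one, at 0.916, and fry called 0. The neutrophil list alone passed with each single array left out, but not without number 2 (adjusted p = 0.349) or number 3 (0.230). The pan-leukocyte list did not pass without PBS replicate 2 (0.185), PBS replicate 3 (0.331), Salmonella replicate 2 (0.125) or Salmonella replicate 3 (0.109). Glucocorticoid-responsive genes lost the call without PBS replicates 2 or 3 (0.273 and 0.583) or Salmonella replicate 3 (0.0513), and immediate early genes without PBS replicates 2 or 3 (0.665 and 0.817) or Salmonella replicate 3 (0.949). The immediate early list also failed after quantile normalisation (0.110), after centring (0.135) and on ranks (0.06). Epidermis markers lost it without the array labelled PBS replicate 1 (0.179) or Salmonella replicate 2 (0.213). Cartilage markers lost it without the array labelled PBS replicate 1 (0.0776), PBS replicate 3 (0.812) or Salmonella replicates 2 or 3 (0.0969 and 0.127), and oxidative phosphorylation genes without PBS replicate 3 (0.583), the array labelled Salmonella replicate 1 (0.331) or Salmonella replicate 3 (0.109). Cartilage markers also failed after quantile normalisation (0.108) and centring (0.0685), and oxidative phosphorylation genes after centring (0.0804). The median of the neutrophil list was 1.13 for number 2, 1.15 for number 3 and -0.86 for number 1.

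In the arrays of numbers 2 and 3 taken alone, transcripts of neutrophils and other leukocytes, mmp13a and irg1l were higher in the Salmonella arrays, and per2 was lower. lyz was 9.79-fold higher, a log2 change of 3.29 (SE 0.13, n = 2 per group, limma adjusted p = 3.83e-05). mpx rose by 2.87 (SE 0.16), srgn, the proteoglycan core protein of leukocyte granules, by 2.35 (SE 0.13), and mmp13a by 2.04 (SE 0.12), with limma adjusted p-values of 0.000211, 0.000211 and 0.000297. irg1l, a relative of the immunoresponsive gene of macrophages that is used here as an epidermal marker, rose by 1.34 (SE 0.15, limma adjusted p = 0.0107). per2, a light-inducible component of the circadian clock, fell by 2.73 (SE 0.20, limma adjusted p = 0.00115). The arrays labelled PBS replicate 1 and Salmonella replicate 1, left out here after their values had been seen, differed the opposite way for each of these 6 genes.

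Of the 32 probe sets past the threshold, 28 were higher and 4 lower. They gave 21 higher and 3 lower genes, 3 further probe sets (mpx, per2 and rgs2) and 5 without a single gene name. For mpx and per2 the representative probe set also passed. For rgs2 it did not, and only another probe set was called (0.96). At an unadjusted p under 0.05 there were 1759. The other genes among the 12 largest increases were si:dkey-102g19.3 (1.75), socs3a (1.74), the actin-bundling lcp1 (1.63), klf2a (1.40), the pan-leukocyte phosphatase ptprc (1.39), coro1a (1.36) and diabloa (1.28), all with a limma adjusted p between 0.00345 and 0.0128. The remaining higher genes were alox5ap, ctss2.1, arrdc2, spi1b, laptm5, serpinh1b, cebpd, cxcr4b and junba, with changes from 0.89 to 1.25. Besides per2, LOC567909 (-1.63) and si:ch211-161h7.5 (-1.47) were lower. The next, cry2 (-0.94, adjusted p = 0.0522) and leap2 (-0.77, adjusted p = 0.0838), did not pass in limma, although both passed without Salmonella replicate 3 (0.00379 and 0.0136) and cry2 also without Salmonella replicate 2 (0.0254). mpx had 4 probe sets with changes from -0.48 to 2.87 and coro1a 2, at 0.13 and 1.36, so the choice of probe set matters for both. With 1 of these arrays left out, the residual spread comes only from the group that keeps 2 arrays. Calls after such an omission depend on which pair sets that spread, and do not show which arrays the calls rest on. irg1l and diabloa lost their calls when PBS replicate 2 or PBS replicate 3 was left out. klf2a lost its call without PBS replicate 2, and si:ch211-161h7.5 without PBS replicate 3.

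**Figure D2:**
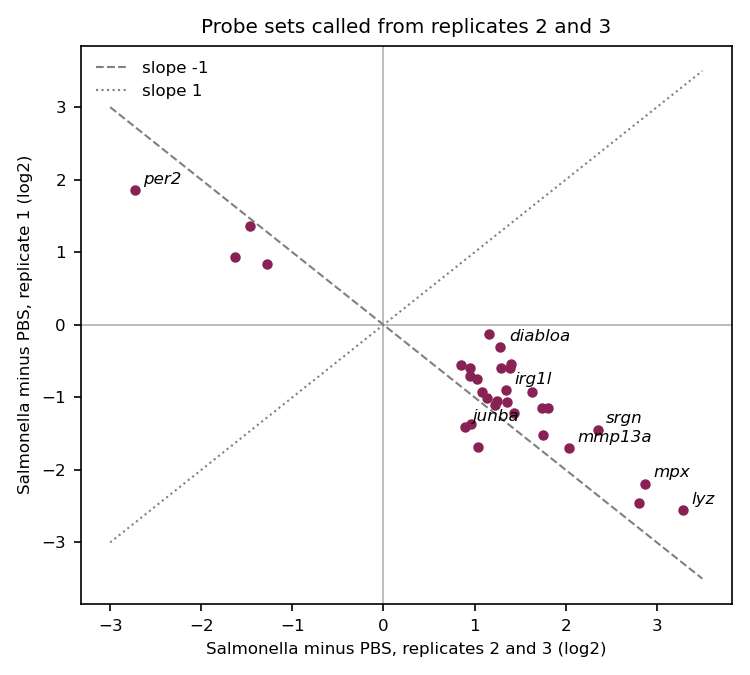
Salmonella minus PBS difference on the log2 scale in replicate number 1 (vertical axis) against the change in numbers 2 and 3 (horizontal axis), with a point for each of the 32 probe sets past the threshold in numbers 2 and 3; the dotted line marks equal and the dashed line opposite differences. All 32 points lie on opposite sides of 0 on the axes, for example lyz at 3.29 and -2.56 and per2 at -2.73 and 1.86.

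Leukocyte lists were higher in the Salmonella arrays of numbers 2 and 3. Of 10 measured neutrophil markers, 6 rose over all probe sets (lyz, mpx, srgn, mmp13a, alox5ap and cxcr4b) and 9 adjusted over the list alone, with a median of 1.13 (camera adjusted p = 1.38e-23, and adjusted p = 0.185 with an estimated correlation). mmp9 and mmp13a belong to this list and also to the metalloproteinases. Of 13 pan-leukocyte markers, 5 rose (lcp1, ptprc, coro1a, spi1b and laptm5) and 9 adjusted over the list alone, with a median of 0.77 (camera adjusted p = 2.08e-15, and adjusted p = 0.185 with an estimated correlation). Macrophage and microglia markers had 1 of 15 members past the threshold, the cathepsin gene ctss2.1 (1.23), and 3 adjusted over the list alone, with a median of 0.19 (camera adjusted p = 5.93e-05, and adjusted p = 0.306 with an estimated correlation). Fry, the one-way test, passed the neutrophil and pan-leukocyte lists (FDR 0.0137 for both) and no other. For the difference of number 1 alone, the list medians were -0.86 for neutrophil, -0.69 for pan-leukocyte and -0.08 for macrophage markers. None of 5 lymphocyte and thymus markers passed, with a median of 0.10 (camera adjusted p = 0.361). The 3' minus 5' difference of the GAPDH control probe sets, a sign of RNA integrity, was 0.67 and 1.04 in PBS replicates 2 and 3 and 1.35 and 1.101 in Salmonella replicates 2 and 3. In number 1 it was 1.497 in the array labelled PBS and 1.27 in that labelled Salmonella. The actin difference was 2.07 and 2.39 in PBS replicates 2 and 3, 2.95 and 2.36 in Salmonella replicates 2 and 3, and 2.45 and 2.38 in the arrays labelled PBS and Salmonella replicate 1.

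Of 7 measured matrix metalloproteinases in numbers 2 and 3, mmp13a alone passed over all probe sets. mmp9, a gelatinase, had a change of 0.61 (SE 0.13, limma adjusted p = 0.175, and 0.0364 without Salmonella replicate 3) and passed with mmp13a when adjusted over the list alone. The membrane-type members mmp14a and mmp14b had changes of 0.10 and 0.18, and the first of these turned to -0.07 without PBS replicate 3. The median of the list was 0.10 (camera adjusted p = 0.0148, and adjusted p = 0.483 with an estimated correlation), and the list did not pass without PBS replicate 3 (median -0.07, adjusted p = 0.0512) or Salmonella replicate 3 (adjusted p = 0.0975), or on ranks (0.228). The 2 measured tissue inhibitors, timp2a (0.37) and timp2b (0.25), did not pass over all probe sets, and timp2a passed adjusted over the list alone.

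No shift of fatty acid beta-oxidation genes against other genes was detected in numbers 2 and 3. None of 27 members passed, over all probe sets or adjusted over the list alone, and the median was -0.09 (camera adjusted p = 0.894, and adjusted p = 0.941 with an estimated correlation). cpt1ab, a carnitine palmitoyltransferase that admits fatty acids to mitochondria, had a change of 0.34 (SE 0.14, limma adjusted p = 0.410), and acsl1a, an acyl-CoA synthetase, of -0.27 (SE 0.14, limma adjusted p = 0.510). cpt1b changed by -0.02, and by 0.02 and 0.03 after quantile normalisation or centring, and hadhaa by -0.11. With both groups at 2 arrays of whole trunks, changes confined to a few cells were not resolved. Of 43 epidermis markers, 1 passed, irg1l, with a list median of 0.05 (camera adjusted p = 0.0092, and adjusted p = 0.628 with an estimated correlation). That list did not pass without Salmonella replicate 2 (adjusted p = 0.177) or PBS replicate 3 (0.0542).

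Among 25 immediate early and stress transcription factors in numbers 2 and 3, 4 rose over all probe sets, namely the cytokine signalling inhibitor socs3a (1.74), klf2a (1.40), cebpd (1.02) and junba (0.89). Adjusted over the list alone, 12 rose, and the median was 0.31 (camera adjusted p = 4.05e-15, and adjusted p = 0.476 with an estimated correlation). cebpb, a transcription factor of the study question, had a change of 0.05 (SE 0.18, limma adjusted p = 0.936). Glucocorticoid-responsive genes had 0 of 14 members past the threshold and 7 adjusted over the list alone, with a median of 0.50 (camera adjusted p = 8.25e-09, and adjusted p = 0.222 with an estimated correlation). nfkbiaa (0.93, limma adjusted p = 0.0838) and tsc22d3 (0.68, limma adjusted p = 0.150) came nearest. For the difference of number 1 alone, the medians of the immediate early and glucocorticoid-responsive lists were -0.56 and -0.24.

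Of the cytokine, interferon, oxidative burst, pattern recognition and complement genes, 1 passed over all probe sets in numbers 2 and 3. None of 14 cytokines and chemokines passed, with a median of -0.03 (camera adjusted p = 0.757) that was 0.01 after quantile normalisation, and the 2 with the smallest p were ccl34b.1 (-0.48) and tnfsf10 (-0.28). Of 22 interferon response and antigen presentation genes, 1 rose, ctss2.1, and 2 adjusted over the list alone, with a median of 0.02 (camera adjusted p = 0.0381, and adjusted p = 0.583 with an estimated correlation), and the list did not pass without PBS replicate 3 (0.186) or Salmonella replicate 3 (0.187), or on ranks (0.182). Oxidative burst and redox genes had 0 of 18 past the threshold, with ncf1, a subunit of the phagocyte oxidase, at 1.01 (limma adjusted p = 0.0522), and a median of 0.02 (camera adjusted p = 0.039, and adjusted p = 0.513 with an estimated correlation), and no call without PBS replicate 3 (0.121), without Salmonella replicate 2 (0.302), after quantile normalisation (0.165) or on ranks (0.0741). Pattern recognition and NF-kB genes had 0 of 11 and 2 adjusted over the list alone, nfkbiaa and nfkbiab (0.53), with a median of -0.04, a mean of 0.14 and camera adjusted p = 0.0558, which was 0.00455 without Salmonella replicate 2. None of 17 complement genes passed (median 0.0036, camera adjusted p = 0.148, and 0.0467 without Salmonella replicate 3), with cfp at 0.49 and c8b at 0.37. Among 21 acute phase and plasma protein genes 0 passed, and adjusted over the list alone 3 were lower and 1 was higher; saa, an acute phase gene of the study question, had a change of 0.06 (SE 0.15).

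Some lists of markers of other trunk tissues also passed. Exocrine pancreas markers, the digestive enzymes of the acinar cells, had a median of -0.33 in numbers 2 and 3 (camera adjusted p = 0.00278, and adjusted p = 0.628 with an estimated correlation), and 0 of 15 members passed, with 2 lower adjusted over the list alone, pla2g1b (-0.66) and cpa4 (-0.54). Per number, that median was -0.06 for number 2, -0.53 for number 3 and 0.69 for number 1, and without PBS replicate 3 the list no longer passed (-0.06, adjusted p = 0.608). The amylase gene amy2a stood at 8.90 and 9.62 in the arrays labelled PBS and Salmonella replicate 1, against 6.96 to 7.37 in the other 4. Skeletal muscle markers had a median of 0.11 (adjusted p = 0.0145, and adjusted p = 0.628 with an estimated correlation), neural markers of 0.08 and cartilage, bone and notochord markers of 0.12 (adjusted p = 0.0341 for both, and adjusted p = 0.628 for both with an estimated correlation), and 0 members of these 3 lists passed. None of these 3 lists passed without PBS replicate 3 (adjusted p = 0.221, 0.426 and 0.810) or after quantile normalisation (0.134, 0.0680 and 0.0594), and the last 2 also failed without Salmonella replicate 3 (0.283 and 0.0533). Neural markers failed with the mean over probe sets as well (0.0553). Erythrocyte markers had a median of -0.08 (adjusted p = 0.184) and passed without Salmonella replicate 2 (-0.22, adjusted p = 0.0104). Liver, intestine, lens and retina, and pigment cell lists had medians of -0.04, -0.03, -0.08 and -0.04 with adjusted p-values of 0.817, 0.275, 0.846 and 0.935, and camera gave the liver, intestine and pigment lists the opposite direction to their medians. In all, 12 lists were higher and 1 lower of 29, and 0 of these 13 held with an estimated correlation. The estimates had both signs, for example -0.061 for neutrophil, -0.080 for pan-leukocyte and 0.775 for exocrine pancreas markers. With the few degrees of freedom of 2 arrays against 2, this check cannot decide which lists hold.

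**Figure D3:**
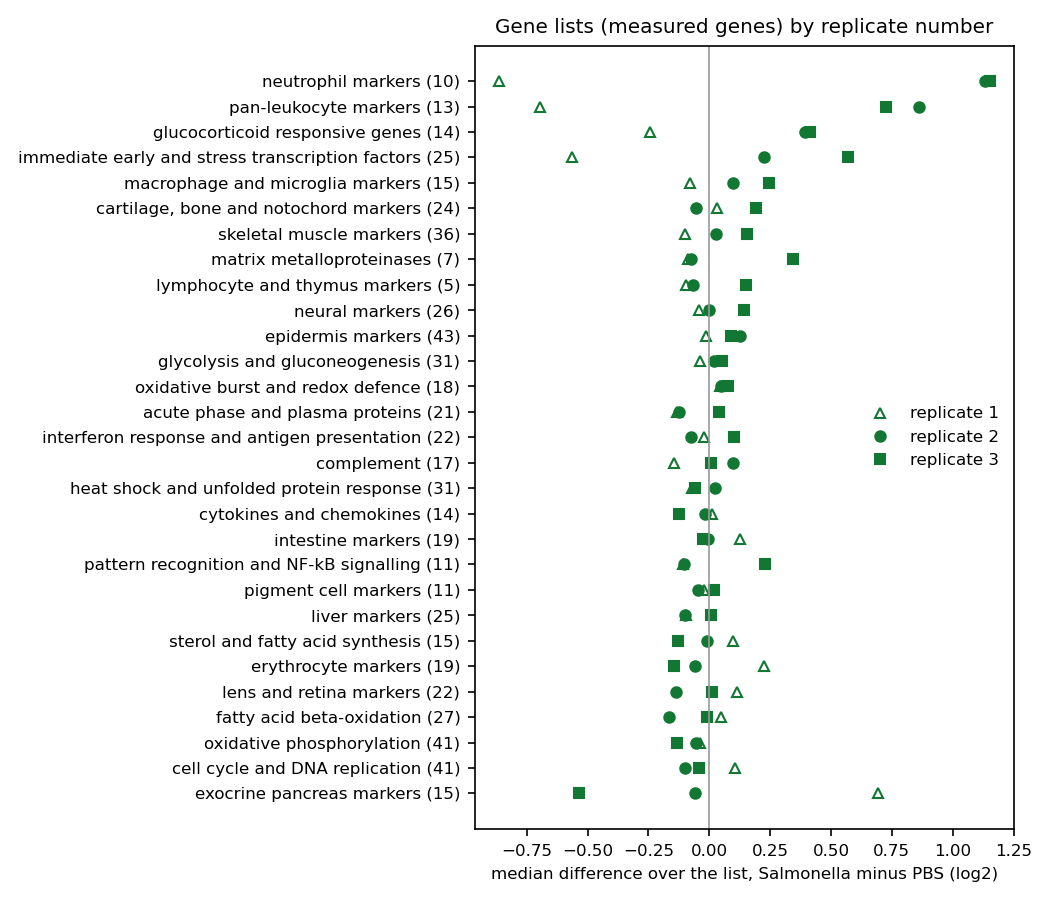
Median Salmonella minus PBS difference on the log2 scale (horizontal axis) over the measured genes of each of the 29 tested lists (vertical axis, number of genes in brackets), for replicate number 1 (open triangles), 2 (circles) and 3 (squares). The neutrophil list is at 1.13 and 1.15 for numbers 2 and 3 and at -0.86 for number 1, and the fatty acid beta-oxidation list at -0.17, -0.01 and 0.05.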

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

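All comparisons in this part were chosen after the values had been seen, and no explanation was tested. A control probe set for the red fluorescent protein DsRed, outside the gene comparisons, stood out because it was higher in 2 of 3 Salmonella arrays, with a Salmonella median 2.36 above the PBS median. Its log2 values were 8.17 and 8.16 in PBS replicates 2 and 3 and 10.52 and 11.12 in Salmonella replicates 2 and 3, but 10.52 in the array labelled PBS replicate 1 and 8.20 in the array labelled Salmonella replicate 1. A second control probe set, whose target is not given in the sources used here, had a Salmonella median 2.66 above the PBS median, with 7.99 and 8.07 in PBS replicates 2 and 3, 10.73 and 11.12 in Salmonella replicates 2 and 3, 10.67 in the array labelled PBS replicate 1 and 8.10 in that labelled Salmonella replicate 1. They were the only 2 of 115 control probe sets whose group medians differed by over 1, and the labels name no fluorescent protein. Both took the signs of lyz in each number, including the reversal in number 1. For numbers 1, 2 and 3, the differences were -2.32, 2.36 and 2.96 for DsRed. They were -2.57, 2.74 and 3.06 for the second probe set, and -2.56, 3.41 and 3.17 for lyz. Control probe sets for EGFP and AsRed lay between 6.32 and 6.71 and between 5.48 and 6.05 in the 6 arrays.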

How the results depend on the processing

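In the comparison as labelled, probe sets and genes stayed at 0 in both directions under each setting chosen in advance, the replicate block and every left-out array included. They moved only with both arrays of number 1 left out, a choice made after seeing the data, to 28 and 4 probe sets and 21 and 3 genes, with 12 lists higher. Lists as labelled, 6 higher and 1 lower, ranged over left-out arrays from 2 to 8 higher and from 0 to 2 lower. The lower list was lost (0) under the replicate block, median centring and without number 3, both counts were 0 with an estimated correlation, and 1 list was higher without number 2 and 2 without number 3. The pancreas list ranged over left-out arrays from -0.69 (turned, without Salmonella replicate 1) to 0.38, and turned to -0.33 without number 1. The immediate early list, with medians from -0.069 to 0.23 over left-out arrays, turned in its test without Salmonella replicate 3 (median 0.00011) and without number 3 (-0.18). Alternatives for numbers 2 and 3 were all added after seeing the data. Against 28 and 4 probe sets and 21 and 3 genes, the replicate block gave 54 and 10, and 33 and 6, a threshold of 0.1 gave 43 and 9, the unmoderated test 0 and 0 (with 2 arrays against 2 its few degrees of freedom make this uninformative), and the mean over probe sets 6 lower genes. Left-out arrays gave 12 to 279 higher and 2 to 307 lower probe sets, 10 to 152 and 2 to 181 genes, and 5 to 12 and 0 to 2 lists, with both extremes of probe sets from leaving out PBS replicates 2 and 3 or Salmonella replicate 3. Each such omission leaves 1 array, assumed to vary like the other group. An estimated correlation left 0 and 0 lists, a check limited by the few degrees of freedom of 2 arrays against 2. All 32 calls were kept under the block, quantile normalisation, centring, array weights and without either Salmonella array, 31 with trended eBayes, 28 without dim probe sets, 14 without PBS replicate 2 and 15 without PBS replicate 3. The replicate numbers were not taken to pair the samples, because the labels do not say what they mark. Deviations of same-numbered arrays from their group means correlated at 0.216, 0.152 and -0.094, with 1 of 3 pairs below 0. These means keep the labels of number 1. If those labels were exchanged, the group difference would push same-numbered arrays apart and lower these correlations. They therefore cannot decide against a pairing. However, 4 of 6 arrays correlated best with their own number, a hint from the data that leaves a pairing open. In their values, the arrays labelled PBS and Salmonella replicate 1 correlated best with each other (r = 0.9955). Both also had high amy2a (8.90 and 9.62). PBS replicates 2 and 3 instead correlated best with each other (0.9959). The unpaired fit leaves any such shared part of a number in the residual spread. Under the replicate block the immediate early and oxidative phosphorylation lists as labelled (adjusted p = 0.06 and 0.0816), and neural markers in numbers 2 and 3 (0.0571), no longer passed, while the macrophage and the oxidative burst lists as labelled (both 0.0359, with 7 higher lists against 6), and cry2 (0.0175) and the pattern recognition list (0.0417) in numbers 2 and 3, did. Signal over background could not be assessed from these values. Where a call changed, the cause was not tested.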

Other observations

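The tests on replicate number 1, on other splits of the arrays and on the clock genes were chosen after the results had been seen. In numbers 2 and 3, no list of plasma protein, lipid or sugar metabolism genes passed. Of 21 acute phase and plasma protein genes 0 passed over all probe sets, but adjusted over the list alone the apolipoprotein gene apoa4a (-0.89), ahsg1 (-0.67) and the haptoglobin gene hp (-0.46) were lower and the antithrombin gene serpinc1 (0.88) was higher, with a list median of 0.02, a mean of -0.05 and camera adjusted p = 0.894. None of 15 sterol and fatty acid synthesis genes passed, with a median of -0.04 (adjusted p = 0.271), and msmo1 (-0.49) and hmgcs1 (-0.46) had the smallest p. None of 31 glycolysis and gluconeogenesis genes passed either (median 0.02, adjusted p = 0.131), with ldha at 0.71 and pck1 at 0.57. Cell cycle and DNA replication genes had a median of -0.11 over 41 members (adjusted p = 0.116), with mcm2 at -0.56 and fen1 at -0.36, and oxidative phosphorylation genes a median of -0.09 (adjusted p = 0.208). In the heat shock and unfolded protein list 1 of 31 genes rose, the collagen chaperone serpinh1b (1.04, limma adjusted p = 0.0231), with a median of -0.0031, a mean of -0.0094 and an upward test (adjusted p = 0.739).

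The difference of replicate number 1 had the opposite sign to those of numbers 2 and 3 in all 32 probe sets called without it. The levels did not always follow. The array labelled Salmonella replicate 1 had lyz near the PBS level, at 8.99. It had diabloa at 9.04, against 8.53 and 8.86 in Salmonella and 7.41 and 7.41 in PBS replicates 2 and 3. For arrdc2 it stood at 8.30, against 8.37 and 8.64 and 7.40 and 7.28. For serpinh1b it stood at 6.83, against 6.91 and 6.97 and 6.01 and 5.78. The slope of the number 1 difference on the change in numbers 2 and 3 was -0.736 (95% bootstrap interval over probe sets -0.795 to -0.673). Probe sets measured on the same arrays are not independent replicates, so such intervals do not measure the spread between samples. Infected larvae of number 1 without a response would leave its PBS array beside the other PBS arrays, but over the 32 largest differences of number 2 alone the array labelled PBS replicate 1 lay toward the Salmonella side of PBS replicate 3 with a slope of 0.754 (95% bootstrap interval over probe sets 0.652 to 0.845), and over those of number 3 it lay 0.848 from PBS replicate 2, against -0.0573 between PBS replicates 2 and 3 over those of number 1, which argues against a missing response alone. An exchange of labels between the arrays of number 1 may account for it. By itself, neither an exchange nor a missing response would place diabloa, arrdc2 and serpinh1b near the Salmonella level in Salmonella replicate 1. Over the 32 largest differences of number 2, the array labelled Salmonella replicate 1 lay toward the PBS side of Salmonella replicate 3. Its slope was -0.718 (95% bootstrap interval -0.858 to -0.551). Over those of number 3, its slope from Salmonella replicate 2 was -0.258 (-0.599 to 0.170), an interval that includes 0. The PBS array was thus out of place over both sets, but the Salmonella array clearly over only 1. For the Salmonella minus PBS differences, the slope over the 32 largest of number 2 alone was -0.63 for number 1 and 0.85 for number 3. Over those of number 3 it was -0.53 for number 1 and 0.58 for number 2. Inflamed PBS larvae together with unresponsive infected larvae remain open, since the 19 of 19 called probe sets outside the leukocyte lists that also opposed could follow inflammation, and an exchange in numbers 2 and 3 instead would give the same slope, so the arrays alone do not settle which labels hold.

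The counts as labelled were set against all 10 splits of the 6 arrays into 3 and 3, which are too few for a share under 0.05. The real counts of probe sets and genes were both 0, the lowest any of the 10 splits can give, so the splits say nothing on them. The highest other counts were 41 and 15. For lists, 7 splits gave at least the real count of 7, and the highest other was 16. Among the splits, the one that exchanges the arrays of number 1 called 22 probe sets. The one that sets the arrays labelled PBS 1, Salmonella 1 and Salmonella 3 against the rest called 41, while the other 8 called 0. As the exchange did not give the most calls, these counts do not single it out, and so few splits cannot settle how the samples group.

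per2 was lower in both Salmonella arrays of numbers 2 and 3 (-2.34 and -3.11) and higher in the array labelled Salmonella replicate 1 (1.86). A different time of day at sampling may be a source. Of 13 measured core oscillator genes, 1 moved by over 0.5 the same way in numbers 2 and 3, namely cry2 (-1.02 and -0.85). As their daily amplitude in these trunks is not known, this cannot be told apart from an effect of infection. Different light exposure before sampling could lower light-responsive genes together, and 5 of 5 were lower in both numbers (per2, cry1a, cry-dash, cry5 and tefa), as were 9 of the 13 core genes, while by the bound of 0.5 it was 1 of 5, per2, which alone passed in limma. These genes were listed after values had been seen, which leaves it open, and an effect of infection on per2 was not tested apart from these.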
